A study of Mus musculus with 2 samples.

How the data were processed

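Single-cell RNA sequencing was done on dissociated whole brains of 6-month-old APP-KI mice, a knock-in model of Alzheimer's disease, in 2 libraries, 1 with intact Fit2 (Fit2-WT) and 1 with mutated Fit2 (Fit2-Mut). Cells were released with an enzymatic adult brain dissociation kit and libraries were built with droplet-based 3' chemistry, per the labels' protocols. The number of animals behind each library and the deleted part of the gene are not given in the labels. The matrices hold UMI counts per gene and barcode, whole numbers with no normalization, per the file headers. Reads were aligned to mm10 with Cell Ranger, version 7.0.0 per the submitters' processing notes and 7.1.0 per the file headers; the annotation release and the handling of intronic reads are not stated in the sources used here. The deposited counts cover all barcodes rather than called cells, with 32285 genes in each library.

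Barcodes were kept as cells with at least 1000 UMIs, at least 500 genes with a UMI and at most 10% mitochondrial UMIs, the same limits in both libraries, and doublets called by Scrublet (in Scanpy 1.11.5) in each library were removed at an expected rate of 0.8% per 1000 barcodes. Of the Fit2-WT barcodes, 5820 passed the UMI and gene limits, 5333 also passed the mitochondrial limit and 124 were removed as doublets, which left 5209 cells. In Fit2-Mut the numbers were 6636, 5979 and 155, which left 5824 cells. Counts of both libraries were log-normalised together, and 2000 variable genes, 30 principal components and 15 neighbours gave 32 Leiden clusters at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0). No integration of the libraries was applied. Clusters were named from 21 fixed marker lists, with at least 3 markers and at least 0.5 of a type's markers required, each at least 2-fold above the other cells and in at least 10% of the cluster. A cluster stayed unnamed where its 10 leading genes held more markers of another type, or where it was shallow and no marker led; names are written as "like" because they rest on markers alone.

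For each type with at least 100 cells in each library, raw counts were summed over cells and divided by the summed total (CPM, the usual scaled count). Ratios are Fit2-Mut over Fit2-WT. With 1 library per group, no p-value, standard error or count of changed genes can be given. Intervals are 95% intervals, exact Poisson for a summed count, exact conditional for a ratio and exact Clopper-Pearson for a share of cells; the interval of a list median comes from 1000 Poisson draws. They cover counting error only, not variation between animals or preparations. Those of counts, ratios and list medians also take each UMI as independent. They are too narrow where a few cells hold many UMIs of a gene. Of a count of 0, the floor used is 3 counts.

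The 30 gene lists were fixed before the data were examined. They cover microglial states (homeostatic microglia, disease-associated microglia, interferon response, MHC class I, MHC class II, complement, cytokines and chemokines, phagocytic receptors, proliferation), lipid handling (lipid droplet, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, cholesterol efflux), organelles and metabolism (ER stress, lysosome, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, cytosolic ribosomal proteins), other cells (reactive astrocyte, homeostatic astrocyte, blood-brain barrier, endothelial activation, myelin, disease-associated oligodendrocyte) and controls (immediate early genes, haemoglobin, sex-linked, and markers of other cells called contaminant for microglia). A list's value is the median log2 ratio over members with at least 20 UMIs in both libraries together, with its percentile among 10000 random lists of the same size matched on mean CPM, which describes these libraries only. All lists were computed in 7 types, 209 values in all, of which 180 had at least 5 members. The text gives 92 of these by a rule set after the values had been seen: all lists with at least 5 members in microglia-like cells, and elsewhere those at or under percentile 1 or at or above percentile 99, with the lipid droplet and interferon lists given in every type.

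Named genes follow a rule fixed before the data were examined: the 10 highest and 10 lowest genes in microglia-like cells, and 5 each way in the other 6 types, ranked by the bound of the ratio's interval nearest to 1. Not every gene picked by the rule is named in the text. They had a ratio of at least 1.5 either way, at least 50 UMIs together, a UMI in at least 5% of cells of the higher library and a CPM there of at least 0.5 times that of barcodes with 10 to 100 UMIs. Ribosomal, mitochondrial, haemoglobin, sex-linked and unnamed gene models were left out. The members shown to illustrate a list are not always those with the most UMIs. Some lie farther from a ratio of 1 than the list median. Of 12 state genes planned for shares per cell, 11 were used; Clec7a was not analysed here. A rule for cycling cells, a UMI of at least 2 of 10 cell-cycle genes, was added after the proliferation list had been seen.

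Alternatives for UMI, gene and mitochondrial limits, doublets, cluster resolution, typing by marker share, scaling (TMM in edgeR 4.0.16 and median of ratios in DESeq2 1.42.0, R 4.3.3), weighting of cells, thinning to 1000 UMIs, free RNA subtraction and list minimums are given in the closing section. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The ratio and interval steps were tested on simulated data built from the microglial sums, over 8696 genes with 50 changed at each size: simulated log2 ratios of 1 and -1 came back with medians of 0.95 and -1.04, and ratios of 2 and -2 with medians of 1.98 and -2.05, with 94% to 98% of the true values inside the intervals. The simulated counts were independent Poisson draws, the model that the intervals assume. The simulation therefore checks the computation and not the width of the intervals where UMIs gather in few cells. Gene positions are from GENCODE vM21 on GRCm38, the assembly also called mm10.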

Results

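The series asked how the transcriptome of brain cells differs when Fit2, a gene of lipid droplet formation, is disrupted in macrophages of mice with an Alzheimer's disease model. The data are 1 single-cell library per genotype from whole brain. The Fit2-WT library held 52491901 UMIs over 822368 barcodes with a UMI, and the Fit2-Mut library held 63234140 UMIs over 868762. The 5209 Fit2-WT cells had a median of 6817 UMIs and 2415 genes, and the 5824 Fit2-Mut cells a median of 7376 UMIs and 2612 genes. There are no replicates, so every difference below is between 2 libraries and cannot be set against variation between animals. Xist had 4 UMIs in the Fit2-WT cells and 7 in the Fit2-Mut cells, against 3727 and 4453 for the Y-linked Ddx3y, so both libraries came largely from males.

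The first question was whether the targeted transcript was lower in microglia, the resident macrophages of the brain. Mouse Fit2 is Fitm2 (ENSMUSG00000048486), which encodes an endoplasmic reticulum protein that partitions triglyceride into lipid droplets. In microglia-like cells Fitm2 had 17 UMIs in Fit2-WT (2.93 CPM, 1.71 to 4.69) and 1 UMI in Fit2-Mut (0.132 CPM, 0.00334 to 0.736), a ratio of 0.0451 (0.00108 to 0.288). The 1 Fit2-Mut UMI is fewer than the floor of 3 counts, and with doublets kept the ratio was 0.161. In barcodes with 10 to 100 UMIs, which read free RNA, Fitm2 had 6.56 and 10.0 CPM. With free RNA subtracted the Fit2-Mut level was set at the floor, which gave a ratio of 0.139 without counting error. In all other cells together Fitm2 had 289 and 352 UMIs, 7.69 and 7.83 CPM, a ratio of 1.02 (0.868 to 1.19). Over all cells, microglia-like ones included, the levels were 7.06 and 6.72 CPM.

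Among the 10 types in which it was counted, Fitm2 was highest in ependymal-like cells, at 40.1 CPM in Fit2-WT and 32.1 in Fit2-Mut (ratio 0.80, 0.520 to 1.23). Astrocyte-like cells had 11.6 and 10.9 CPM, oligodendrocyte-like cells 8.32 and 8.17, choroid plexus-like cells 5.48 and 5.31, and endothelial-like cells 6.37 and 6.34. Border-associated macrophage-like, monocyte-like and neutrophil-like cells had no Fitm2 UMI in either library, so no loss could be detected there at this depth. Fitm2 lies on chromosome 2, 163466379 to 163472629 on the minus strand, with 2 exons and a 3' untranslated region of 3127 bases. A 3' tag may fall outside the altered part of the gene, in which case the count reads the level of the transcript and not the presence of the mutation. Its paralog Fitm1 had 2 UMIs in microglia-like cells of each library, under the floor. App (ENSMUSG00000022892), the knock-in gene of the model, had 162 CPM in microglia-like cells of Fit2-WT and 163 in Fit2-Mut (ratio 1.01, 0.928 to 1.10).

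**Figure D1:**
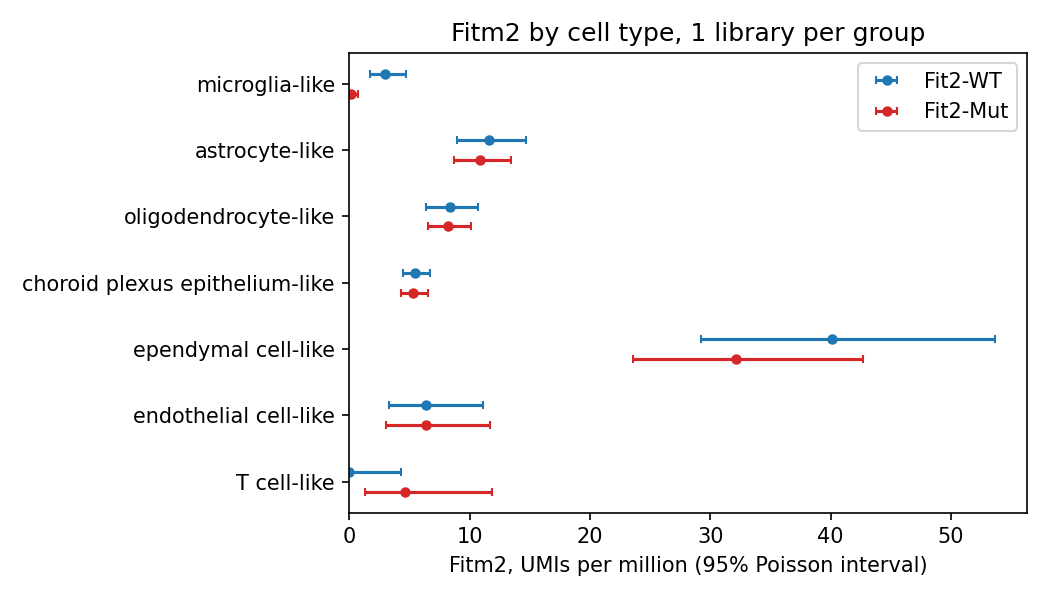
Fitm2 in CPM (x axis) by cell type (y axis) in the Fit2-WT and Fit2-Mut libraries, with 95% Poisson intervals as bars. The microglia-like points lie at 2.93 and 0.132, while the intervals of both libraries overlap in the other types drawn.

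The second question was whether the make-up of the brain cell suspension differed. Microglia-like cells were 10.6% of Fit2-WT cells (550 cells) and 10.0% of Fit2-Mut cells (585 cells), a share ratio of 0.951 (0.845 to 1.07). Endothelial-like cells had a lower share in the Fit2-Mut library, 8.31% against 5.87% (ratio 0.706, 0.611 to 0.816). Neuroblast-like cells, the migrating precursors of olfactory interneurons, had a higher share, 1.42% against 2.68% (ratio 1.89, 1.42 to 2.52). Monocyte-like cells were 1.27% and 0.738% (ratio 0.583, 0.387 to 0.869).

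The largest groups differed less. Choroid plexus-like epithelium made up 27.7% and 25.6% (ratio 0.926, 0.861 to 0.996), astrocyte-like cells 21.7% and 23.5% (1.08, 1.0 to 1.17) and oligodendrocyte-like cells 14.1% and 16.0% (1.13, 1.02 to 1.25). With types assigned by marker share per cell the oligodendrocyte-like ratio turned to 0.990. Ratios were 0.899 (0.730 to 1.11) for T cell-like cells, 1.13 (0.875 to 1.47) for ependymal-like cells, 0.772 (0.504 to 1.18) for border-associated macrophage-like cells and 0.779 (0.544 to 1.11) for neutrophil-like cells. For NK cell-like and B cell-like cells they were 0.681 (0.426 to 1.08) and 1.42 (0.938 to 2.18). Dissociation and capture of each suspension also set these shares, and 1 suspension per genotype cannot separate them from composition in the brain.

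The main comparison concerned gene programs in microglia-like cells, summed to 5803650 UMIs in Fit2-WT and 7572265 in Fit2-Mut. Cell-cycle genes and antigen presentation genes were higher in the Fit2-Mut library, and the lipid droplet program that Fitm2 belongs to was close to level. The proliferation list had a median log2 ratio of 1.73 (1.42 to 2.04; percentile 100), with 15 of 19 members at least 1.5-fold higher and none lower by that much. Mki67, a marker of dividing cells, had 7.24 CPM in Fit2-WT and 49.0 in Fit2-Mut (ratio 6.77, 4.91 to 9.55), Top2a, the topoisomerase of chromosome segregation, 11.03 and 62.7 (5.69, 4.37 to 7.51), and Stmn1 66.0 and 191 (2.90, 2.59 to 3.26). These intervals take each UMI as independent and leave out variation between cells. Without 1 cluster led by cell-cycle genes, of 4 Fit2-WT and 19 Fit2-Mut cells, the median was 0.39 over 13 members, and without the 10 cells per library with most list UMIs it was 2.03 over 18. With all 19 members it was 1.01 with doublets kept, 1.05 at most 5% mitochondrial UMIs and 0.80 with cells weighted equally, and with cells thinned to 1000 UMIs 0.30, over 5 members that had 0.78 unthinned. At equal depth, 4 of 550 Fit2-WT cells (0.727%, 0.199 to 1.85) and 18 of 585 Fit2-Mut cells (3.08%, 1.83 to 4.82) met the rule for cycling cells; unthinned, 9 and 33 cells did.

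MHC class II genes, which present antigen to CD4 T cells, were higher by a median log2 ratio of 0.42 (0.38 to 0.50; percentile 100), with all 7 members above a ratio of 1. H2-Aa had 336 and 508 CPM (ratio 1.51, 1.43 to 1.60), H2-Eb1 215 and 329 (1.53, 1.43 to 1.64) and the invariant chain Cd74 1533 and 2026 (1.32, 1.29 to 1.36). Thinned to 1000 UMIs per cell, H2-Aa had a UMI in 10.5% (8.11 to 13.4) of Fit2-WT and 16.2% (13.3 to 19.5) of Fit2-Mut microglia-like cells, against 0.231% and 0% (up to 1.07) of endothelial-like cells. Unthinned, the shares were 26.0% and 33.8% in microglia-like cells, at median depths of 9812.5 and 11538 UMIs, and 0.693% and 1.46% in endothelial-like cells, at 3910 and 3949.5. MHC class I genes had a median of 0.26 (0.22 to 0.37; percentile 100), with 11 of 11 members above 1, among them H2-K1 at 640 and 837 CPM (1.31, 1.26 to 1.36).

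Genes of the disease-associated state, which microglia switch on around amyloid plaques, were slightly lower in the Fit2-Mut library, with a median of -0.08 (-0.10 to -0.07, percentile 0) over 34 members and 8 of them above 1. Of the 34 members, 33 lay within 1.5-fold. The median was -0.03 in thinned cells and -0.15 with TMM scaling. The most abundant, Apoe, which encodes a lipid carrier, had 22656 and 17724 CPM (ratio 0.782, 0.776 to 0.788). Spp1, encoding osteopontin, had 1852 and 1461 CPM (0.789, 0.768 to 0.810), Fabp5, a fatty acid carrier, 674 and 455 (0.676, 0.645 to 0.708), and Igf1 355 and 269 (0.756, 0.711 to 0.804). B2m and Cd52 went the other way, at ratios of 1.17 and 1.20. Despite its lower CPM, Spp1 had a UMI in 16.2% of Fit2-WT and 18.5% of Fit2-Mut cells at equal depth, with overlapping intervals. A cluster led by Spp1 and Lpl held 308 of the 550 Fit2-WT and 348 of the 585 Fit2-Mut cells. Another, low in Malat1 and with Cst7 and Trem2 among its leading genes, held 139 and 115. The disease-associated list took a median of 8.95% of a cell's UMIs (quartiles 5.70 and 12.1) in Fit2-WT and 8.26% (5.46 and 11.4) in Fit2-Mut. Homeostatic genes had a median of 0.07 (0.05 to 0.12, percentile 91.2), which turned to -0.00 with TMM or median of ratios scaling and to -0.01 with thinned cells. Without the cluster low in Malat1, of 139 Fit2-WT and 115 Fit2-Mut cells, the homeostatic median was 0.03.

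Shares of cells with a UMI of other state genes lay close together at equal depth. Cst7 was found in 63.1% and 60.0% of microglia-like cells, Itgax in 12.7% and 14.4%, Spp1 in 16.2% and 18.5%, Lpl in 33.6% and 33.8%, and Gpnmb in 7.27% and 7.52%. P2ry12 was found in 42.9% and 45.8%, and Tmem119 in 22.9% and 23.2%. In endothelial-like cells, the background here, these 7 genes were found in at most 1.17% of cells. Unthinned shares were 79.1% and 80.2% for Cst7 and 31.8% and 41.0% for Spp1. Apoe was found in 82.5% and 80.7% of microglia-like cells against 59.6% and 58.5% of endothelial-like cells. Plin2, at 8.91% (6.66 to 11.6) and 7.01% (5.08 to 9.39), overlapped endothelial-like cells at 7.39% (5.11 to 10.3) and 7.31% (4.79 to 10.6). Ifit3, at 1.09% and 1.37%, lay below the 9.47% and 8.19% of endothelial-like cells, so neither gene is read as a microglial difference.

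The lipid programs next to Fitm2 were compared because its protein feeds lipid droplets. The lipid droplet list had a median of 0.05 (-0.07 to 0.10; percentile 32.8), with 1 of 20 members at least 1.5-fold higher. Plin2, which coats droplets, had 92.2 and 89.7 CPM (ratio 0.973, 0.867 to 1.09), Soat1, which esterifies cholesterol, 142 and 138 (0.968, 0.883 to 1.06), and Dgat1, which makes triglyceride, 11.4 and 8.72 (0.766, 0.537 to 1.09). Fatty acid synthesis had a median of -0.17 (-0.26 to 0.10; percentile 0.43), fatty acid oxidation 0.06 (-0.03 to 0.17) and cholesterol efflux -0.07 (-0.13 to 0.01). Cholesterol synthesis was at 0.23 (0.07 to 0.34; percentile 97.2), with 16 of 20 members above 1, such as Hmgcs1 at 24.0 and 34.5 CPM (1.44, 1.17 to 1.78). ER stress genes, which respond to misfolded protein in the compartment that holds the Fitm2 protein, had a median of 0.05 (-0.01 to 0.09; percentile 50.9), and lysosome genes -0.01 (-0.04 to 0.02).

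Interferon response genes in microglia-like cells had a median of 0.17 (0.02 to 0.26; percentile 97.49) with members on both sides: Ifi27l2a had 245 and 411 CPM (ratio 1.68, 1.58 to 1.79), Isg15 48.8 and 30.2 (0.620, 0.519 to 0.741). The median turned to -0.09 in thinned cells and to -0.01 with cells weighted equally. Phagocytic receptors were at 0.07 (-0.01 to 0.15), cytokines and chemokines at 0.03 (-0.05 to 0.15), complement at -0.02 (-0.08 to 0.15), immediate early genes at -0.07 (-0.10 to -0.03) and glycolysis at -0.02 (-0.08 to 0.02). Nuclear oxidative phosphorylation had -0.08 (-0.12 to -0.07), cytosolic ribosomal proteins -0.07 (-0.08 to -0.06) and mitochondrially encoded genes 0.05 (0.02 to 0.07). The last turned to -0.01 with TMM scaling, and immediate early genes turned to 0.04 in thinned cells. Ribosomal proteins also had negative medians in every other type compared, the smallest -0.012 in choroid plexus-like cells. So did nuclear oxidative phosphorylation in all but astrocyte-like cells, where it was at 0.008. Some lists of other cells share members with microglial lists, so they do not read only RNA from outside microglia. Such members are Apoe in reactive astrocyte, B2m in disease-associated oligodendrocyte and Cd74 in endothelial activation. Medians of the lists of other cells were -0.60 (-0.79 to -0.26) for myelin, 0.24 (0.10 to 0.38) for reactive astrocyte and 0.26 (0.02 to 0.38) for homeostatic astrocyte. They were 0.10 (0.07 to 0.19) for disease-associated oligodendrocyte, 0.02 (-0.07 to 0.27) for blood-brain barrier, 0.16 (0.00 to 0.38) for endothelial activation and 0.23 (-0.01 to 0.53) for the contaminant list. Of these, myelin turned to 0.05 at 500 UMIs and 250 genes and homeostatic astrocyte to -0.38 with free RNA subtracted, and endothelial activation to -0.02 over members with at least 1 UMI in each library. Over all 12073 genes the median log2 ratio was 0.07, with 5% of genes under -0.47 and 5% above 0.83.

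**Figure D2:**
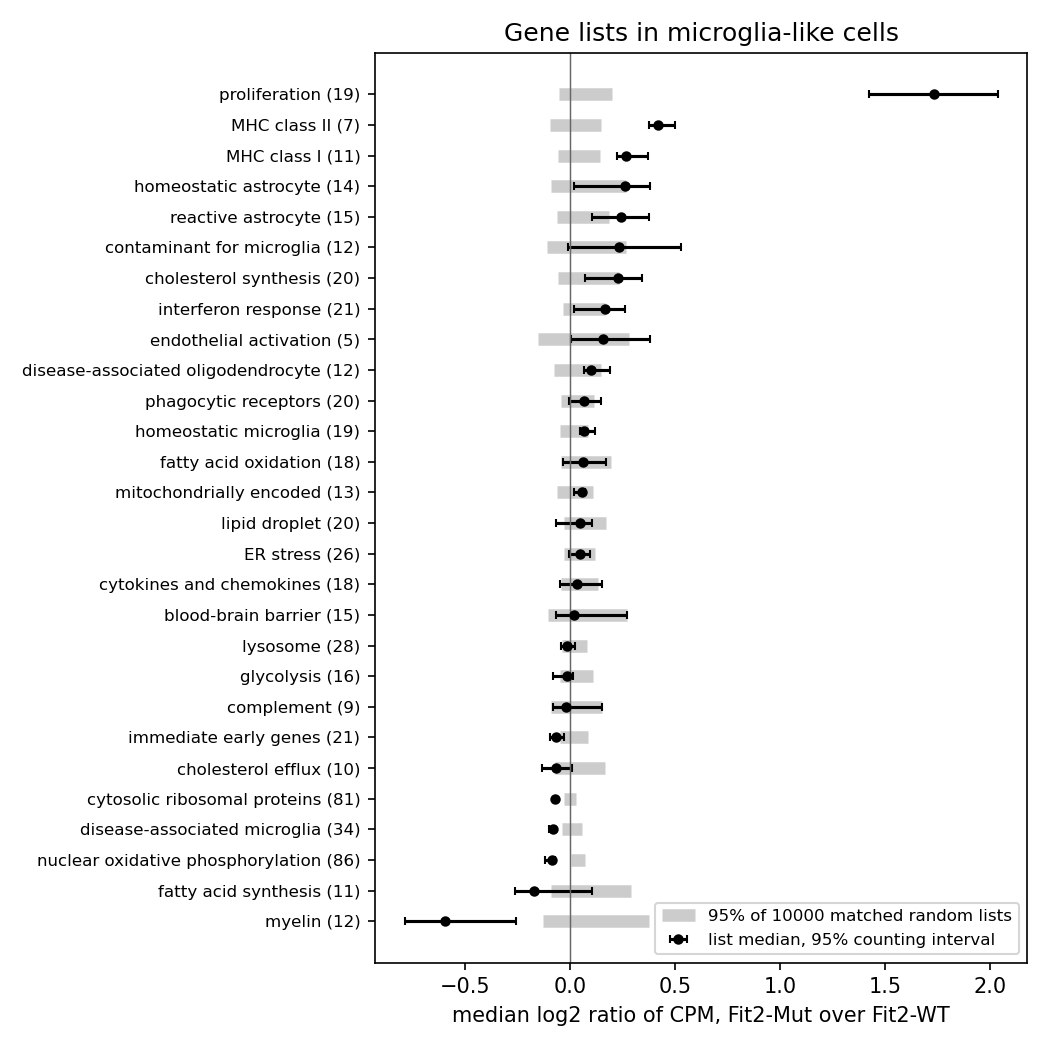
Median log2 ratio of CPM, Fit2-Mut over Fit2-WT (x axis), of each gene list with at least 5 measured members in microglia-like cells (y axis, members in brackets). Points are list medians with 95% counting intervals and grey bars hold 95% of 10000 matched random lists; proliferation lies at 1.73, MHC class II at 0.42 and lipid droplet at 0.05. The homeostatic microglia median of 0.07 turns sign under TMM or median of ratios scaling.

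Of the genes picked by the ratio rule, Fn1 (ENSMUSG00000026193), which encodes fibronectin, had 13 UMIs in Fit2-WT and 122 in Fit2-Mut microglia-like cells, a ratio of 7.19 (4.05 to 13.9), with 50% of the Fit2-Mut UMIs in 5 cells. The rule did not leave out members of the state lists. Dkk2, Isg15 and Crybb1 below belong to the disease-associated, interferon and homeostatic lists. The other 9 highest genes serve mitosis or the cell cycle or DNA damage signalling, Cenpe, Cenpa, Cdca8, Racgap1, Kif20b, H2afx, Tacc3, Cenpp and Cks1b, with ratios from 2.76 to 5.21. From 34.4% to 49.5% of the Fit2-Mut UMIs of each lay in 5 cells. Whether these were the same cells for all 9 genes was not tested. Cenpe, a kinetochore motor, had 25 and 170 UMIs (5.21, 3.41 to 8.28). The lowest genes were Ankrd55 with 39 and 15 UMIs (0.295, 0.151 to 0.547), the adhesion gene Ctnna3 with 2644 and 2254 (0.653, 0.617 to 0.691), the Wnt antagonist Dkk2 with 497 and 407 (0.628, 0.549 to 0.717), and Isg15, with 56.5% of its Fit2-WT UMIs in 5 cells and a UMI in 14.7% of Fit2-WT and 20.2% of Fit2-Mut cells, followed by Tcim, Crybb1, Elmod2, Sirt6, Polr2l and Fhad1 with ratios from 0.50 to 0.665.

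The last question was whether cells that were not the target differed as well. Choroid plexus-like epithelium, which makes cerebrospinal fluid, had higher interferon response genes in the Fit2-Mut library, with a median of 0.47 (0.35 to 0.71, percentile 100) and 14 of 15 members above 1. The median was 1.04 with types by marker share, and 0.34 in thinned cells, over 7 members. Ifitm3 had 53.4 and 81.8 CPM (ratio 1.53, 1.41 to 1.67) and Bst2 140 and 178 (1.27, 1.21 to 1.34). Isg15, at a low level, had 0.477 and 3.26 (6.84, 3.23 to 16.6), far above the median fold of the list, 1.39. In endothelial-like cells the same list was lower, at -0.19 (-0.30 to -0.10; percentile 0.12), with 2 of 18 members above 1, Ifitm3 at 1525 and 1338 CPM (0.877, 0.829 to 0.929) and Isg15 at 381 and 289 (0.759, 0.674 to 0.855).

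In the other types the interferon intervals included 0. The medians were 0.49 (-0.02 to 0.70) in oligodendrocyte-like cells, 0.24 (-0.08 to 0.38) in astrocyte-like cells, 0.20 (-0.13 to 0.39) in ependymal-like cells and 0.12 (-0.08 to 0.41) in T cell-like cells. The oligodendrocyte-like median turned to -0.10 over members with at least 100 UMIs, and the astrocyte-like one to -0.09 without 2 clusters low in ribosomal UMIs. MHC class I genes had medians of 0.62 (0.51 to 1.28) in oligodendrocyte-like, 0.32 (0.18 to 0.53) in astrocyte-like and 0.26 (0.11 to 0.34) in choroid plexus-like cells, with 9 of 9, 10 of 10 and 9 of 9 members above 1. B2m, the light chain of MHC class I, had 47.9 and 73.4 CPM in oligodendrocyte-like cells (1.53, 1.35 to 1.75) and 43.8 and 61.9 in astrocyte-like cells (1.41, 1.21 to 1.65). In barcodes with 10 to 100 UMIs B2m had 291 and 396 CPM.

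**Figure D3:**
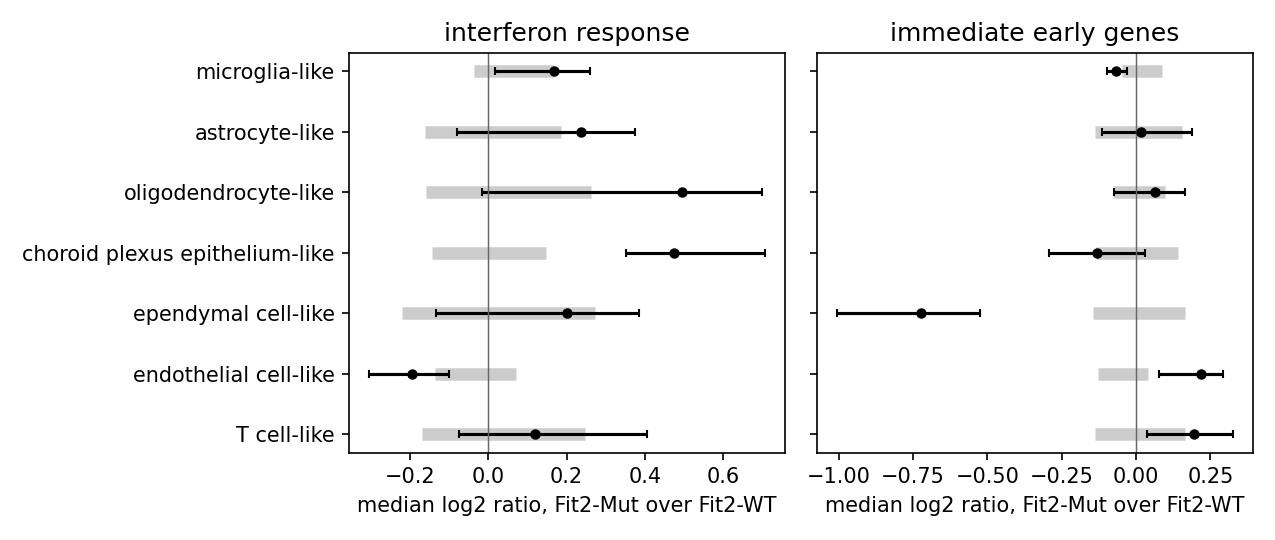
Median log2 ratio, Fit2-Mut over Fit2-WT (x axes), of the interferon response list (left) and the immediate early genes (right) in 7 cell types (y axis). Points are medians with 95% counting intervals and grey bars hold 95% of matched random lists; interferon genes lie at 0.47 in choroid plexus-like and -0.19 in endothelial-like cells, and the oligodendrocyte-like and astrocyte-like medians turn sign under some alternatives.

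The lipid droplet list was near 0 in 5 other types, at -0.01 (-0.09 to 0.08) in astrocyte-like, -0.00 (-0.05 to 0.11) in oligodendrocyte-like, -0.04 (-0.11 to 0.04) in choroid plexus-like, -0.01 (-0.20 to 0.13) in endothelial-like and -0.05 (-0.23 to 0.14) in ependymal-like cells. In T cell-like cells it had a median of 0.23 (-0.18 to 0.50), with 10 of 14 members above 1. Astrocyte-like cells, which supply cholesterol to neurons, had higher cholesterol synthesis genes, with a median of 0.25 (0.14 to 0.28; percentile 100) and 19 of 20 members above 1. Msmo1 had 357 and 451 CPM (1.26, 1.20 to 1.33). The astrocyte-like clusters differed in balance between the libraries. A cluster led by Agt and Itih3 held 255 Fit2-WT and 440 Fit2-Mut cells, and another held 286 and 224. Differences over this type, in lists and in named genes, also read this balance. Other astrocyte-like medians were 0.44 (0.02 to 0.68) for complement, 0.38 (0.12 to 0.75) for cytokines and chemokines, 0.36 (0.04 to 0.51) for phagocytic receptors, 0.15 (0.03 to 0.25) for the disease-associated oligodendrocyte list, 0.09 (0.03 to 0.13) for ER stress, 0.09 (0.05 to 0.15) for lysosome, 0.07 (0.02 to 0.09) for homeostatic astrocyte, -0.06 (-0.08 to -0.04) for ribosomal proteins and -0.50 (-0.69 to -0.16) for the contaminant list. With free RNA subtracted, complement turned to -0.45, phagocytic receptors to -0.05 and ribosomal proteins to 0.42. ER stress, lysosome and homeostatic astrocyte turned to -0.01, -0.02 and -0.01 without 2 clusters low in ribosomal UMIs, cytokines and chemokines to -0.08 without 10 cells per library, and the contaminant list to 0.02 with types by marker share.

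The genes highest relative to Fit2-WT in astrocyte-like cells were Slc43a2, an amino acid transporter, at 27.7 and 50.2 CPM (ratio 1.81, 1.5 to 2.19), then Irx2, Fam155a, A2m and Nalcn, with ratios from 1.69 to 2.05. The lowest were Fbxo32, a ubiquitin ligase gene, at 30.1 and 13.8 CPM (0.459, 0.357 to 0.587), Rpe65, Ptchd4, Capn11 and Zscan29. Oligodendrocyte-like cells, which make myelin, had Ust, Ndst4, Tnfrsf12a and Mbd4 among the highest, with ratios from 2.08 to 2.56; Ust, a sulfotransferase gene, had 88 and 257 UMIs (2.08, 1.63 to 2.68). Ankrd37, Zfp512b, Zgrf1, Ccdc187 and Cyp4f17 were lowest there, with ratios from 0.463 to 0.552.

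Medians of further lists in oligodendrocyte-like cells were 0.17 (0.02 to 0.20) for disease-associated microglia, 0.46 (0.19 to 1.04) for cytokines and chemokines, 0.40 (0.08 to 0.64) for phagocytic receptors, 0.48 (0.08 to 0.59) for reactive astrocyte and 0.14 (0.08 to 0.20) for disease-associated oligodendrocyte. Among microglial genes in them, Tyrobp had 6.14 and 9.72 CPM, against 642 and 742 in barcodes with 10 to 100 UMIs. With free RNA subtracted, the first 3 of these medians turned to -0.04, -0.06 and -0.17. Cholesterol synthesis was at -0.07 (-0.12 to 0.02), cholesterol efflux at 0.14 (-0.01 to 0.21), ER stress at 0.07 (0.02 to 0.11), blood-brain barrier at -0.16 (-0.32 to 0.04) and ribosomal proteins at -0.06 (-0.06 to -0.04).

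In choroid plexus-like cells Rsrp1, which encodes an arginine and serine rich protein, stood highest, at 147 and 306 CPM (ratio 2.08, 1.99 to 2.19), with a UMI in 68.5% and 86.8% of cells. Nsg1 had 36.0 and 65.8 CPM (1.83, 1.65 to 2.02), and Ifitm3, Ifi27l2a and Tapbpl followed. Bmp4, a secreted growth factor, was lowest at 14.1 and 8.88 CPM (0.628, 0.508 to 0.775), with Sebox, Gtsf1l, Sptb and Zscan12. ER stress genes had a median of 0.19 (0.11 to 0.21; percentile 100), with the chaperone Hspa5 at 767 and 888 CPM (1.16, 1.13 to 1.19). Mitochondrially encoded genes were at 0.19 (0.16 to 0.19), nuclear oxidative phosphorylation at -0.06 (-0.06 to -0.05), lysosome at 0.05 (0.01 to 0.10), cytokines and chemokines at 0.29 (-0.05 to 0.48), disease-associated microglia at 0.11 (0.07 to 0.19; -0.32 with types by marker share), blood-brain barrier at 0.11 (0.03 to 0.17) and myelin at 0.40 (0.13 to 0.62).

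Endothelial-like cells had a higher median of immediate early genes, 0.22 (0.08 to 0.29; percentile 100), and of endothelial activation genes, 0.35 (0.14 to 0.77), with 8 of 9 members above 1; the latter turned to -0.07 in thinned cells. Egr1, an immediate early transcription factor, had 37.7 and 101 CPM (2.69, 2.02 to 3.61), with 39.4% of its Fit2-Mut UMIs in 5 cells. Socs3, a brake on cytokine signals, had 13.8 and 37.4 CPM (2.71, 1.68 to 4.48), with 47.5% of its Fit2-Mut UMIs in 5 cells. Car5a, Tmem252 and Eln followed, and Eln had 75.2% of its Fit2-Mut UMIs in 5 cells. Gja4, a connexin of arteries, was lowest at 31.9 and 6.34 CPM (0.199, 0.0908 to 0.392), with 50% of its Fit2-WT UMIs in 5 cells, then Ppcs, Tspyl4, the mural cell gene Rgs5 and H2-T24. With doublets kept, disease-associated microglia, at 0.30 (0.13 to 0.49), and phagocytic receptors, at 0.30 (0.10 to 0.64), turned to -0.07 and -0.23. Other medians were 0.17 (-0.00 to 0.26) for lysosome, 0.20 (-0.06 to 0.58) for the contaminant list, -0.15 (-0.18 to -0.11) for nuclear oxidative phosphorylation and -0.13 (-0.15 to -0.12) for ribosomal proteins.

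Ependymal-like cells, which line the ventricles, had lower immediate early genes in the Fit2-Mut library, with a median of -0.72 (-1.01 to -0.52; percentile 0) and 12 of 20 members lower by at least 1.5-fold; the median was -0.39 in thinned cells, over 4 members, and -0.42 without 10 cells per library. Fos had 390 and 160 CPM (ratio 0.410, 0.348 to 0.482), Jun 505 and 251 (0.497, 0.435 to 0.568) and Egr1 78.4 and 21.2 (0.270, 0.173 to 0.411). Among the highest genes were Zfp804b, Ptx4, Npy and Isg15, with ratios from 2.77 to 6.42; 62.7% of the Fit2-Mut UMIs of Zfp804b, 52.5% of those of Npy and 85.7% of those of Isg15 came from 5 cells each. Btbd17, Wfdc2, Sspo, Rbp4 and Spp2 were lowest, with ratios from 0.0973 to 0.280, and 84.1% to 94.2% of their Fit2-WT UMIs came from 5 cells each. Nuclear oxidative phosphorylation was at -0.21 (-0.25 to -0.17), ribosomal proteins at -0.13 (-0.16 to -0.11), cholesterol efflux at 0.31 (0.07 to 0.34), disease-associated microglia at 0.23 (0.07 to 0.32), disease-associated oligodendrocyte at 0.26 (0.01 to 0.34), the contaminant list at 0.35 (-0.38 to 0.45) and myelin at -1.02 (-1.48 to -0.62), which turned to 0.55 in thinned cells. The thinned myelin value rests on 1 member. In thinned cells disease-associated microglia turned to -0.06, and disease-associated oligodendrocyte turned to -0.04 without 10 cells per library.

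T cell-like cells, 185 in Fit2-WT and 186 in Fit2-Mut, had a receptor gene at the head of their lower genes. They lay in 2 clusters, 1 led by Cd3g and Ccl5 with 135 and 158 cells and 1 led by Il7r with 50 and 28, so differences over the type also read this balance. Trav8n-2, a T cell receptor alpha variable segment, had 53 UMIs in Fit2-WT and 0 in Fit2-Mut, with 62.3% of the Fit2-WT UMIs in 5 cells. With the 0 set at a floor of 3 counts over the type it was 17.7-fold lower, and the upper bound of its ratio was 0.0721. Dapl1, Aff3, Nsg2 and Satb1, a chromatin organiser, were lower, at ratios from 0.342 to 0.537, and Bpgm, Gpd2, Umad1, Ier3 and Stx8 were higher, at 2.22 to 3.91, with 79.1% of the Fit2-Mut UMIs of Bpgm and 67.2% of those of Ier3 in 5 cells each. Haemoglobin genes made up 2.52% of the Fit2-Mut UMIs of this type, with 99.9% of these in 5 cells. Whether those cells also held the Bpgm UMIs was not tested. Cytokines and chemokines had a median of 0.43 (0.30 to 0.60), cholesterol efflux -0.44 (-0.73 to -0.08), nuclear oxidative phosphorylation -0.10 (-0.17 to -0.07), ribosomal proteins -0.17 (-0.19 to -0.16) and the contaminant list 0.69 (0.18 to 1.16), which turned to -0.24 with doublets kept. The T cell cholesterol efflux median rests on 7 members and turned to 0.33 over the 2 with at least 100 UMIs.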

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

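The tests of RNA from microglia, of a shift over all cells, of choroid plexus-like cells without 10 cells and of random doublets below, and the interval asked of the median without 10 cells, were chosen only after the results were seen, as were the size of 0.15 and the clear counting intervals by which list medians were picked out here. Differences between cell types were not tested, since there is 1 library per genotype.

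A list was picked out where its median was at least 0.15 higher in Fit2-Mut in some type and at least 0.15 lower in another, with neither interval reaching 0. Interferon response genes were lower in endothelial-like cells, at -0.19, and higher in choroid plexus-like epithelium, at 0.47. Immediate early genes were lower in ependymal-like cells, at -0.72, and higher in endothelial-like cells, at 0.22. Cholesterol efflux genes were lower in T cell-like cells, at -0.44, and higher in ependymal-like cells, at 0.31. Myelin genes were lower in ependymal-like cells, at -1.02, and higher in choroid plexus-like cells, at 0.40, both types that make no myelin. The contaminant list was lower in astrocyte-like cells, at -0.50, and higher in T cell-like cells, at 0.69. The directions of 3 of these 5 contrasts turn with the processing: the contaminant list was at 0.018 in astrocyte-like cells with types by marker share and -0.24 in T cell-like cells with doublets kept, T cell-like cholesterol efflux lay between 0.33 and 0.42 under 3 alternatives, and ependymal-like myelin between 0.20 and 1.15 under 4. Of these values, cholesterol efflux rests on 2 members at 100 UMIs and on 3 in thinned cells, and myelin in thinned cells on 1. A cluster left without a type, outside the comparisons of the report, carried microglial and T cell genes and held 39 Fit2-Mut cells and 9 Fit2-WT cells.

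Interferon response genes had positive medians in choroid plexus-like, oligodendrocyte-like and astrocyte-like cells, though only the choroid plexus-like interval lay clear of 0. A shift over all cells of the library is argued against by the endothelial-like median of -0.19, whose upper bound is -0.10. That value also helped to pick out this list, so it is not independent evidence. A few cells with many list UMIs are argued against in choroid plexus-like cells, at 0.47 (0.36 to 0.63) without the 10 cells per library that held most, and stay open in the other 2 types, where the lowest median was 0.24 (-0.02 to 0.43), in astrocyte-like cells. RNA from microglia in other cells stays open: the homeostatic microglia bound lay under the interferon median in 2 of the 3 types, and in astrocyte-like cells it reached 0.35. The genotype may also account for the choroid plexus-like median, and 1 library per genotype leaves that untested.

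Cells with both microglial and T cell genes, counted before doublets were removed as at least 5 microglial and 3 T cell marker UMIs, were 28 of 5333 in Fit2-WT and 62 of 5979 in Fit2-Mut, a ratio of 1.98 (1.25 to 3.21). Random doublets predict a ratio of 0.857 from the relative sizes of both groups, with no allowance for more doublets among more barcodes. The lower bound lies above that but under 1.5 times it, so the bound set for excluding random doublets was not met. The marker UMI limits were the same in both libraries, while microglia-like cells had a median of 9812.5 UMIs in Fit2-WT and 11538 in Fit2-Mut. More multiplets of all kinds in the Fit2-Mut library stay open too, since cells with microglial and oligodendrocyte genes had a ratio of 1.28 (0.729 to 2.28), against 1.08 from random pairs, and those with microglial and endothelial genes 1.43 (0.609 to 3.52), against 0.673; both intervals overlap that of the T cell pair. Contact of microglia with T cells may also give such pairs, and no test of it was run.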

How the results depend on the processing

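The settings that leave out or add single clusters, or leave out the 10 cells with most list UMIs, were chosen after seeing the data; the other alternatives were fixed before. The results whose smaller moves are printed were also picked after the values were seen. No paired analysis was possible because there is 1 library per genotype. A value counts as reversed only where its interval in the report excluded no difference and the alternative lay on the other side. Other changes of sign count as moved, or as stayed where they lay within the interval. The gene ratios cover Fitm2 and the genes picked by the rule in microglia-like cells, which lay far from 1 by that choice. Of 148 share ratios under the alternatives, 144 stayed within the counting interval, 3 moved beyond it and 1 reversed; of 1581 list medians, 1282 stayed, 247 moved and 52 reversed; of 269 gene ratios, 229 stayed, 40 moved and none reversed; all 22 ratios of state gene shares stayed. Cells kept ran from 4262 to 5588 in Fit2-WT and from 4645 to 6318 in Fit2-Mut, all within 1.5-fold of the numbers in the report. The Fitm2 ratio in microglia-like cells lay between 0.0335 and 0.161 and, apart from 0.161 with doublets kept, rests on 1 Fit2-Mut UMI, fewer than the floor of 3 counts. With free RNA subtracted it was 0.139, a value set by that floor and no bound on the ratio. Thinning gave no ratio, as both counts were at or under the floor. MHC class II stayed positive in microglia-like cells, from 0.30 to 0.52, MHC class I from 0.15 to 0.28 and disease-associated genes negative, from -0.15 to -0.03. Proliferation there stayed positive but ran from 0.30 to 2.03. Interferon genes stayed positive in choroid plexus-like cells, from 0.34 to 1.04, and negative in endothelial-like cells, from -0.20 to -0.15, but ran from -0.09 to 0.43 in microglia-like, from -0.30 to 0.59 in oligodendrocyte-like and from -0.09 to 0.60 in astrocyte-like cells. Except where stated, the cause was not tested for the values that follow, which moved or reversed.

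With TMM scaling, microglia-like medians were 0.20 for MHC class I, 0.35 for MHC class II, -0.15 for disease-associated, -0.00068 for homeostatic and -0.012 for mitochondrially encoded genes, and with median of ratios 0.20, 0.35, -0.15, -0.00053 and -0.012. With a total lacking mitochondrial, ribosomal and haemoglobin genes, disease-associated genes were at -0.10 and homeostatic genes at 0.048. With each cell weighted equally, microglia-like medians were 0.22 for MHC class I, -0.059 for disease-associated, 0.045 for homeostatic, 0.0019 for immediate early, -0.0088 for interferon, 0.082 for myelin and 0.80 for proliferation genes, and ribosomal proteins in astrocyte-like cells were at 0.00058.

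At 500 UMIs and 250 genes, microglia-like medians were 0.30 for MHC class II, -0.10 for disease-associated, 0.025 for homeostatic and 0.049 for myelin genes. At 2000 UMIs and 1000 genes they were 0.22 for MHC class I, -0.12 for disease-associated, 0.027 for homeostatic and 1.22 for proliferation genes. With a UMI minimum set in each library, disease-associated genes were at -0.11, homeostatic at 0.030, proliferation at 1.13, ependymal-like myelin at 0.20 and the endothelial-like share ratio at 0.560. At most 5% mitochondrial UMIs gave 0.36 for MHC class II, 0.043 for homeostatic and 1.05 for proliferation genes in microglia-like cells, 0.0048 for astrocyte-like ribosomal proteins and 0.22 for ependymal-like myelin. At most 20% gave 0.43 for microglia-like interferon genes and -0.022 for the contaminant list in T cell-like cells.

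With doublets kept, microglia-like MHC class II was at 0.36 and proliferation at 1.01, the T cell-like contaminant list at -0.24, astrocyte-like ribosomal proteins at 0.0082, ependymal-like myelin at 1.15, disease-associated microglia at -0.072 in endothelial-like and -0.0019 in oligodendrocyte-like cells, and phagocytic receptors at -0.23 and -0.012 in these 2 types. With types by marker share, microglia-like medians were 0.21 for MHC class I and 0.35 for MHC class II, and others 0.42 for T cell-like cholesterol efflux, 0.018 for the astrocyte-like contaminant list, -0.32 for disease-associated microglia and 1.04 for interferon genes in choroid plexus-like cells, and -0.50 for ependymal-like immediate early genes; the oligodendrocyte-like share ratio was 0.990.

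Thinning to 1000 UMIs leaves fewer members per list, and only 1 for ependymal-like myelin. Microglia-like medians were then 0.15 for MHC class I, 0.33 for MHC class II, -0.028 for disease-associated, -0.011 for homeostatic, 0.037 for immediate early, -0.089 for interferon, 0.12 for lipid droplet, -0.022 for homeostatic astrocyte and 0.30 for proliferation genes, the last over 5 of 19 members. Interferon genes were at 0.34 in choroid plexus-like cells and -0.30 in oligodendrocyte-like cells. Disease-associated microglia were at -0.0019 in endothelial-like and -0.061 in ependymal-like cells, phagocytic receptors at -0.021 in astrocyte-like and -0.53 in oligodendrocyte-like cells, endothelial activation at -0.074, T cell-like cholesterol efflux at 0.37, and ependymal-like immediate early genes at -0.39 and myelin at 0.55.

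The free RNA share subtracted was estimated at 11.6% of astrocyte-like UMIs in Fit2-WT and 2.85% in Fit2-Mut, and genes left under the floor were set at it. Astrocyte-like medians were then -0.45 for complement, 0.42 for ribosomal proteins, 0.60 for interferon and -0.045 for phagocytic receptors; oligodendrocyte-like ones were -0.060 for cytokines and chemokines, -0.038 for disease-associated microglia and -0.17 for phagocytic receptors, and the homeostatic astrocyte list in microglia-like cells was at -0.38. Over members with at least 100 UMIs, T cell-like cholesterol efflux was at 0.33, on 2 members, and in oligodendrocyte-like cells disease-associated microglia at -0.0051 and interferon at -0.10. Over members with at least 1 UMI in each library, endothelial activation in microglia-like cells was at -0.021.

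Without the 10 cells with most list UMIs, microglia-like medians were 0.52 for MHC class II, 0.33 for interferon, -0.17 for homeostatic astrocyte and 0.16 for myelin genes, cytokines and chemokines were at -0.081 in astrocyte-like and -0.047 in oligodendrocyte-like cells, and in ependymal-like cells immediate early genes were at -0.42 and disease-associated oligodendrocyte genes at -0.042. Without the cell-cycle cluster, MHC class II was at 0.35, disease-associated genes at -0.061 and proliferation at 0.39 over 13 of 19 members, a move partly built in because the cluster was picked by genes of that list. Without the low-Malat1 cluster, of 139 Fit2-WT and 115 Fit2-Mut cells, MHC class II was at 0.35 and homeostatic genes at 0.029. With the unnamed microglia and T cell cluster, MHC class II was at 0.35, disease-associated genes at -0.11 and homeostatic genes at 0.048. Without the astrocyte-like clusters low in ribosomal UMIs, medians there were -0.013 for ER stress, -0.0074 for homeostatic astrocyte, -0.093 for interferon and -0.019 for lysosome genes.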

Other observations

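The tests of free RNA from dividing cells, of a small cluster of cycling cells and of the share of cycling cells at equal depth, and the rule for cycling cells, were chosen only after the proliferation list was seen, as were the reasons for leaving open the tests by thinning and by removal of 10 cells.

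Haemoglobin genes, which mark red blood cells, lay mostly in 5 cells in some types and were spread over more cells in others. In microglia-like cells, 5 cells held 10.3% of haemoglobin UMIs in Fit2-WT and 6.31% in Fit2-Mut. In T cell-like cells of Fit2-Mut haemoglobin genes made up 2.52% of UMIs, with 99.9% of these in 5 cells, and in endothelial-like cells 3.82%, with 93.8% in 5 cells. In Fit2-WT the shares of UMIs were 0.00232% and 0.743%. In astrocyte-like cells they made up 0.268% of UMIs in Fit2-WT, with 99.3% in 5 cells, and 0.00435% in Fit2-Mut. The median log2 ratio of the haemoglobin list, with 4 members, was 10.47 in T cell-like, 2.35 in endothelial-like, 0.98 in choroid plexus-like, -6.03 in astrocyte-like and 0.73 in microglia-like cells. The sex-linked list, also with 4 measured members, was at 0.16 (-0.03 to 0.31) in microglia-like cells.

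Cell-cycle genes had a median log2 ratio of 1.73 in microglia-like cells, Fit2-Mut over Fit2-WT. Free RNA from other dividing cells is argued against for the members measured elsewhere, since the highest median of the list in astrocyte-like, oligodendrocyte-like and choroid plexus-like cells was 0.079, with an upper bound of 0.37. These medians rest on 8, 8 and 11 of the 19 members. In T cell-like cells, with all 19 measured, the median was -0.04 (-0.35 to 0.13). These cells may express cell-cycle genes themselves, which would mask free RNA, so that value decides nothing here. Depth as the source of more cycling cells is argued against by their share at equal depth, with a ratio of 4.23 (1.39 to 17.2), on 4 and 18 cells. Depth stays open for the size of the list median: the test set beforehand, thinning to 1000 UMIs, gave 0.30, under the bound of 0.5 that depth as the cause would meet, but over 5 of 19 members, which had a median of 0.78 unthinned, and thinning also weights cells equally, which alone gave 0.80 over all 19, so the drop cannot be assigned to depth. A few cells with many list UMIs cannot be told apart from a wider difference by removing 10 cells per library, which gave 2.03, because Fit2-WT held 9 cycling cells by the rule, fewer than were removed; removing the cluster led by cell-cycle genes, of 4 and 19 cells, gave 0.39 over 13 members and decides nothing further, as the cluster was picked by genes of the list. A larger dividing fraction of microglia in the mutant brain may account for this, and so may chance between animals or capture, which 1 library per genotype leaves untested.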
